A study of Coturnix japonica with 54 samples.

How the data were processed

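The samples were 54 male Japanese quail (Coturnix japonica), a bird whose reproductive axis is switched on and off by day length. The labels place the birds in 9 photoperiod groups of 6. Days shortened from 16 h of light to 8 h and lengthened again to 16 h, with 2 weeks at each of 9 steps. Per the labels, a group name holds the hours of light and the arm of the cycle; a was read as the declining (autumnal) arm and v as the rising (vernal) arm, and 8L is the turning point between them. Every sample is labelled as mediobasal hypothalamus, the brain region that holds the neuroendocrine response to day length, and the RNA was sequenced on Oxford Nanopore flow cells. The labels pair no birds between groups and give no batch or date.

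The 2 tables used hold 1 column per bird, and both were made by the authors. The first, called the CPM table here, holds deposited CPM (counts scaled to 1e6 per library) for 19930 genes after 14 names that a spreadsheet had turned into dates were left out. Each of its columns sums to 1e6. Its values below a few CPM are whole multiples of the most common positive value, which returned the reads behind each column. Between 99.72% and 100% of the values per library were whole within 0.1 read. The second, called the count table, holds deposited estimated read counts (expected counts, not normalised) for 40282 transcripts of 16448 genes, and 99.72% of its values are whole within 1e-9. All 40282 transcripts are in the RefSeq annotation table of quail assembly Coturnix japonica 2.1, and 58.3% of the names in the CPM table are in it. The submitters' notes name minimap2 2.17, Salmon 0.14.2 and edgeR 3.24.3; which step each tool took, and the genome build, are not given in the sources used here. No genome coordinates are therefore reported.

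Library size differed between the tables. The reads recovered from the CPM table ranged from 251382 to 1895627 per library (median 938816), and the totals of the count table from 4834 to 156500 (median 39688). Any read counted at several features would enter the recovered totals more than once. A count of 0 over a group was read as a limit of 3 counts of that group's summed total. Such limits cover counting error only, since PCR copies are not independent molecules.

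For the CPM table, 2 columns of the 16Lv group, replicates 3 and 6, differed by less than the sampling noise of their reads (chi-square per gene and degree of freedom 0.954, against 6.85 for the next most similar pair of 135 pairs within groups). They were averaged and counted as 1 sample, which left 53 libraries and 5 in 16Lv. In the count table the lowest such value within a group was 7.57 and all 54 libraries were used. Of 1296 pairs of libraries from different groups 24 had a lower value there, down to 3.6 for 10Lv replicate 5 and 14Lv replicate 5, which have few transcripts. Below 6.85 lay 10 such pairs of the CPM table, down to 6.35.

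The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined, when a single table of counts was foreseen. Counts were summed per gene. For the count table the planned test was run: edgeR 4.0.16 quasi-likelihood F tests (glmQLFit, robust = FALSE) with TMM factors and filterByExpr over the 9 groups (minimum count 10), which kept 826 genes. The CPM table holds another unit than the design foresaw, so there limma 3.58.1 (limma-trend) was run on log2 of TMM-scaled CPM plus a pseudocount of 1, for the 8268 genes with a CPM of at least 10 in at least 6 libraries. Each table had 1 fit of 9 group means with no covariate. Contrasts were 8L minus 16La, 16Lv minus 8L, 16Lv minus 16La, the mean of 10Lv, 12Lv and 14Lv minus the mean of 10La, 12La and 14La, each of those 3 pairs, each step against the step before, linear slopes on hours of light over all 9 groups and over 10 to 16 h in each arm (without 8L, so that the arms shared no library), and the difference between the arms' slopes. Slopes are in log2 units per hour of light. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Log2 changes come from these fits; levels are CPM of the library total for the priority genes below, and TMM-scaled CPM for other genes, as mean ± SD.

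For each of the 4 main comparisons (8L minus 16La, 16Lv minus 8L, rising minus declining, and the slope) the rule named up to 12 called genes per direction by smallest p, filled up to 5 with the next genes by p when fewer passed. In other tests up to 6 called genes were named. Features without a gene symbol were passed over by the rule; LOC107319226 was called in the count table and is named after its values were seen. A further 20 priority genes of photoperiod, pituitary and energy balance biology were tested whatever their level, on log2 of library-total CPM plus 1, with exact two-sided permutation tests between groups and permutation tests of 100000 resamples for the difference among groups, the slope and rising minus declining, adjusted over the priority genes in each table. LHB was in neither table, 19 of the 20 were in the CPM table and 15 in the count table. The smallest p of a resampled test is 1e-05, and that of a test of 6 against 6 libraries is 0.00216.

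The 26 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. A list needed 3 measured members, which held for 24 lists in the CPM table and 4 in the count table. Recovery was tested on simulated data: known changes were put into counts drawn to match each table. For 8L minus 16La the CPM table's test recovered 29.9% of 2-fold, 49.3% of 4-fold and 81.8% of 8-fold changes, and the count table's test 4.48%, 26.9% and 51.5%. For rising minus declining the shares were 62.7%, 83.6% and 92.4% against 31.3%, 73.1% and 83.3%. For the slope, with the fold set over the whole range of day lengths, the shares were 41.8%, 85.1% and 93.9% against 11.9%, 47.8% and 75.8%. Genes with no change made up 3 of 110 calls for 8L minus 16La, 9 of 168 for rising minus declining and 8 of 155 for the slope in the CPM table. For the count table they made up 5 of 60, 16 of 141 and 9 of 99. The threshold allows 5%, which the calls for 8L minus 16La in the CPM table alone stayed under. With no change put in, the CPM table's test called 0 genes in each comparison, and the count table's test called 2 for the difference among groups, 1 for rising minus declining, 1 for the slope and 2 over the successive steps. All simulated genes were drawn independently of each other, so structure shared by the real libraries was not in these data.

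Alternatives planned beforehand were DESeq2 size factors, library totals, no filter, a mean of at least 20, DESeq2 1.42.0, limma-voom with sample quality weights, robust edgeR, a pseudocount of 0.25, 2 surrogate variables (sva 3.50.0), leaving out shallow libraries, fitting only the groups compared, and leaving out each library in turn. Chosen after the data were seen were edgeR, DESeq2 and limma-voom on the recovered reads of the CPM table, the column position within a group as a block, transcripts in place of genes, leaving out 9 libraries of the count table with under 2500 detected transcripts, keeping the near-identical 16Lv columns apart, putting 8L in both arms, and leaving out each library in turn in the permutation tests of slopes. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The results for some named genes are not reported here.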

Results

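Gene expression was measured in samples labelled as mediobasal hypothalamus from 54 male quail, 6 in each of 9 groups that followed 1 simulated year of day lengths: 16La, 14La, 12La, 10La, 8L, 10Lv, 12Lv, 14Lv and 16Lv. The CPM table held 251382 to 1895627 recovered reads per library, with 8544 to 13554 genes detected. The count table was far shallower, with 544 to 9757 genes detected. Its median total was 75566 in 16La and 27128 in 16Lv. Replicates 3 and 6 of 16Lv in the CPM table differed by less than the sampling noise and were counted as 1 sample, so n = 5 for that group there.

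The 2 tables gave different profiles. The CPM table was rich in neuronal transcripts such as MAP2, a microtubule protein of neurons, with 3.31 ± 0.698% of reads (SD, n = 53). The 36 features without a symbol and with a mean above 4000 CPM summed to 33.3 ± 4.68%. Many of them had the same values. LOC121107020 and LOC121107017 each had 1.31 ± 0.214%, and LOC121106998 and LOC121107005 each had 0.539 ± 0.108%. If the same reads were counted at several of them, 33.3% is not a share of distinct reads, which was not tested. The CPM table held 8387 reads of NPY and 2536 of VIP, which encode hypothalamic neuropeptides, and 3452 of NPVF, which encodes gonadotropin-inhibitory hormone. It held 39 reads of PRL (prolactin) and 1 read of FSHB, the beta subunit of follicle-stimulating hormone (FSH). ACOT9, an acyl-CoA thioesterase, took 31.3 ± 11.3% of the counts of the count table (SD, n = 54). Pituitary hormone transcripts were abundant in it: 51567 counts of POMC, the precursor of the melanocortins, 36000 of PRL, 12442 of CGA, the alpha subunit shared by the glycoprotein hormones, and 632 of FSHB, beside 32 counts of NPY and 6 of VIP. Each comparison is therefore given per table.

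The first test asked which transcripts differed among the 9 groups. For the count table CGA, FSHB, PRL and LOC107319226, a protein-coding feature without a symbol that was named after its values were seen, were called of 826 genes (edgeR adjusted p = 3.72e-10 for CGA, 5.31e-07 for FSHB and 1.63e-06 for PRL), and POMC was not. CGA averaged 7890 ± 3088 CPM in 14La, 1033 ± 338 in 12La, 1405 ± 348 in 8L and 7957 ± 3760 in 12Lv (SD, n = 6 each). Limma called 3 of 8268 genes in the CPM table: FABP9, a fatty acid binding protein (adjusted p = 0.000468 in limma), KIFC2, a kinesin motor (0.00721), and C7H2ORF66 (0.0124). The KIFC2 call was lost with limma-voom, with edgeR on the recovered reads and without the 6 shallowest libraries (highest adjusted p = 0.473 over its alternatives), and the C7H2ORF66 call with a pseudocount of 0.25 or without 14La replicate 2 (up to 0.219). Without 8L replicate 3 the count was 5.

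Among the priority genes of the CPM table, 5 of 19 differed between groups in permutation tests of 100000 resamples over 53 libraries. TSHB, the beta subunit of thyrotropin, a signal of long days, had an adjusted p of 0.00665. DIO2, which activates thyroid hormone, and DIO3, which inactivates it, each had 0.0268. POMC and AGRP, peptide precursors of arcuate neurons that lower and raise feeding, each had 0.00735. TSHB rested on 24 reads, 20 of them in 16Lv, and DIO3 on 11 reads, 8 of them in 8L. With TMM-scaled CPM, 7 genes passed, with CGA and NPY added. Of 15 in the count table FSHB, CGA and PRL passed (adjusted p = 5.00e-05 each, from the smallest p that the resampling can give).

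**Figure D1:**
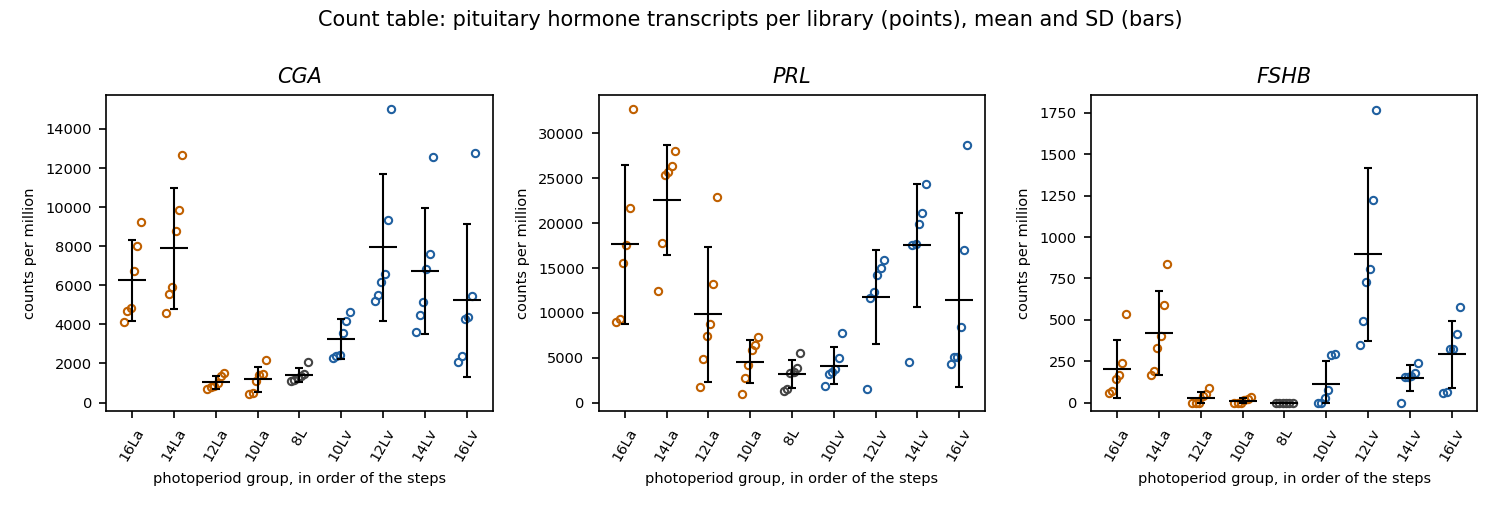
CPM of the library total (vertical axes) of CGA, PRL and FSHB in the count table, for the 9 photoperiod groups in the order of the steps (horizontal axes). Open points are single libraries (6 per group, orange for the declining arm, blue for the rising arm, grey for 8L); the long dash is the mean and the bars are 1 SD, stopped at 0. FSHB was at 0 in the 6 libraries of 8L and averaged 896 in 12Lv, and CGA averaged 1033 in 12La and 7957 in 12Lv.

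The first main comparison asked what had changed by the shortest day, at 8L against 16La. In the count table CGA, PRL and FSHB fell, as did LOC107319226, and edgeR called no gene as higher. CGA fell from 6264 ± 2066 to 1405 ± 348 CPM (SD, n = 6 each; log2 change -2.19, SE 0.36; edgeR adjusted p = 0.000153), and the lowest 16La library (4106) lay above the highest of 8L (2070). PRL fell from 17641 ± 8843 to 3179 ± 1573 CPM (log2 change -2.58, SE 0.45, adjusted p = 0.000262), with 8995 as the lowest value in 16La and 5576 as the highest in 8L. FSHB had counts in 6 of 6 libraries of 16La (202 ± 176 CPM) and in 0 of 6 of 8L, where 0 of 247636 counts allows up to 12.1 CPM (adjusted p = 0.00028). LOC107319226 had a log2 change of -3.86 (SE 0.83, adjusted p = 0.005), a call lost with limma-trend at either pseudocount and with no filter (adjusted p up to 0.535). Of 6 pituitary cell markers 3 fell and 0 rose, with the same 3 genes when adjusted over the list alone. The list was lower in camera (adjusted p = 1.85e-10, and adjusted p = 1.01e-05 with an estimated correlation). POMC, also on that list, had a log2 change of 0.17 (SE 0.53). In exact permutation tests FSHB, CGA, PRL and DIO2 passed (adjusted p = 0.00812 each, 6 against 6). DIO2 stood higher in 8L than in 16La there (54.4 against 10.7 CPM), on 76 counts in all libraries together. The FSHB call was lost when only the 2 groups compared were fitted (adjusted p = 0.0756).

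Of genes without a call in that comparison, ZC3H7B had the smallest adjusted p on the higher side (log2 change 4.93, SE 1.33; edgeR adjusted p = 0.0903), and KCNMA1, a calcium-activated potassium channel, on the lower (log2 change -6.26, SE 1.79; adjusted p = 0.136). NAV2 (log2 change 5.90), CACNA1D, EVL, PTPRK and MEF2A had adjusted p from 0.163 to 0.689. Cytosolic ribosomal proteins, the structural proteins of the ribosome, had 43 of 72 members on the positive side with none called and none when adjusted over the list alone (median log2 change 0.09; camera adjusted p = 0.0247, and adjusted p = 0.663 with an estimated correlation).

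For 8L minus 16La limma called 0 of 8268 genes of the CPM table, with 350 at an unadjusted p under 0.05. DESeq2, limma-voom and edgeR on the recovered reads each called 0, and 1 was called without 8L replicate 3. On the lower side TSPAN2 had a log2 change of -0.85 (SE 0.27) and GPR62 of -1.35 (SE 0.41). On the higher side POMC had a log2 change of 1.28 (SE 0.37), APOA1 of 0.59 (SE 0.17), SPI1 of 2.51 (SE 0.74) and NEURL1 of 1.64 (SE 0.49). Each of these 6 genes had a limma adjusted p of 0.998. PCBP4 (log2 change -2.89, SE 0.87) and LZIC (-1.50, SE 0.48) did not pass either. Microglia and macrophage markers were positive in 6 of 6 members (median log2 change 0.90), with CD74 at 0.77 (SE 0.49) and C1QC at 1.03 (SE 0.78). No member was called and 1, SPI1, the transcription factor of myeloid cells, passed when adjusted over the list alone (adjusted p = 0.00832). The list was higher in camera (adjusted p = 0.0179), and not with an adjusted p = 0.198 with an estimated correlation. When adjusted over their lists alone, POMC and APOA1 also passed.

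The second main comparison asked what had changed on return to long days, at 16Lv against 8L. FSHB and CGA rose in the count table. FSHB went from 0 of 6 libraries to 6 of 6 (293 ± 203 CPM, SD; edgeR adjusted p = 0.000435), and CGA from 1405 ± 348 to 5224 ± 3922 CPM (log2 change 1.73, SE 0.36, adjusted p = 0.00522). PRL had 11428 ± 9713 CPM in 16Lv (log2 change 1.63, SE 0.44, adjusted p = 0.1) and NELL2, a secreted neural protein, a log2 change of 2.07 (SE 0.71, adjusted p = 0.317). CTNND2, PHF3, NBEA, AP2B1, ZBTB38 and TANC2 had adjusted p from 0.0979 to 0.312, each with 0 counts or nearly so in 1 of the groups. Of 6 pituitary cell markers 2 rose, and 3 with PRL when adjusted over the list alone (camera adjusted p = 2.47e-08, and adjusted p = 7.73e-05 with an estimated correlation). In exact permutation tests FSHB and DIO2 (adjusted p = 0.0162 each), CGA (0.0216) and PRL (0.0325) passed, with DIO2 lower in 16Lv (7.44 CPM, or 3.93 without replicate 2) than in 8L (54.4 CPM). Of 5 nuclear genes of oxidative phosphorylation, the mitochondrial respiratory chain, 5 were positive and none passed, also when adjusted over the list alone, led by NDUFB3 (log2 change 1.78, SE 1.00; camera adjusted p = 0.0087, and adjusted p = 0.0951 with an estimated correlation). Both gene calls were lost when only the 2 groups were fitted (adjusted p = 0.376 for FSHB), and the CGA call also with no filter, with limma-voom (adjusted p up to 0.393), and without 16Lv replicate 2 or without 8L replicate 1, 2 or 6, each of which left 1 call.

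For 16Lv minus 8L limma called 0 of 8268 genes of the CPM table, with 447 at an unadjusted p under 0.05, DESeq2 1, and limma-voom and edgeR on the recovered reads 0. Without 16Lv replicate 4 limma called 2, and 1 without 16La replicate 4, 14La replicate 2 or 6, 16Lv replicate 2, or the joined replicates 3 and 6. FABP9 came nearest, at 6.13 ± 6.86 CPM in 16Lv (SD, n = 5) and 19.3 ± 4.96 in 8L (SD, n = 6; log2 change -2.03, SE 0.40; limma adjusted p = 0.0575, from 0.0224 to 0.944 over its alternatives). PNPLA6, a phospholipase of neurons, had a log2 change of 4.83 (SE 1.09) and MAPK8IP1, a scaffold of the JNK pathway, of -2.42 (SE 0.54), both with adjusted p = 0.142. PTGDS, which makes prostaglandin D2, had 164 ± 51.5 CPM in 16Lv and 83.5 ± 20.7 in 8L (log2 change 0.92, SE 0.26, adjusted p = 0.649), and passed when adjusted over the meningeal and fibroblast markers alone (adjusted p = 0.00556), a list with 3 of 7 members positive. ZNF212, NCEH1 and EPB41L4A on the higher side and BIRC8, KLHL25 and PAQR8 on the lower had adjusted p from 0.331 to 0.729. PDYN, the dynorphin precursor, had a log2 change of 0.97 (SE 0.33). None of 24 lists passed in camera (smallest adjusted p = 0.364).

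At 16Lv against 16La, the same day length after and before the cycle, FABP9 and MAPK8IP1 fell in the CPM table. FABP9 fell from 36.5 ± 11.3 CPM (SD, n = 6) to 6.13 ± 6.86 (SD, n = 5; log2 change -2.88, SE 0.40; limma adjusted p = 3.52e-05), and MAPK8IP1 from 44.3 ± 16.1 to 13.3 ± 12.5 (log2 change -2.71, SE 0.54, adjusted p = 0.0296). The FABP9 call was lost with limma-voom and when only the 2 groups were fitted (adjusted p up to 0.917), and the MAPK8IP1 call in 7 of 14 alternatives and without 16La replicate 2, 3, 5 or 6 or 16Lv replicate 1 or 5, each of which left 1 call. No list passed (smallest adjusted p = 0.286). For the count table edgeR called 0 of 826 genes, with 48 at an unadjusted p under 0.05, and DESeq2, limma-voom and limma-trend each called 0. Cytosolic ribosomal proteins there had 43 of 72 members on the negative side with none called, also when adjusted over the list alone (median log2 change -0.053). Camera compares a list with the other genes and ranked this one above them (adjusted p = 0.00549, and adjusted p = 0.541 with an estimated correlation). The median log2 change over all 826 genes was -0.282, so a list with a negative median and mean can rank higher.

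The third main comparison asked whether the direction of change mattered at the same day length. Birds of the rising arm were also sampled at later steps, so direction and time in the study run together here. In the count table CGA was higher on the rising arm as a mean over 10, 12 and 14 h (log2 change 1.21, SE 0.20, 18 libraries against 18, edgeR adjusted p = 0.000249). At 14 h taken alone its mean was not higher on that arm, with 6716 ± 3215 CPM in 14Lv and 7890 ± 3088 in 14La. Of the 3 day lengths edgeR called CGA at 12 h alone. There it was at 7957 ± 3760 CPM in 12Lv and 1033 ± 338 in 12La (log2 change 2.79, SE 0.37, adjusted p = 8.95e-07), with the lowest library of 12Lv (5175) above the highest of 12La (1505). FSHB was at 896 ± 523 CPM in 12Lv and 30.1 ± 36.8 in 12La (18.2 without 12La replicate 3; log2 change 4.55, SE 0.88, adjusted p = 0.00137), and LOC107319226 had a log2 change of 4.44 (SE 0.85, adjusted p = 0.00137), which was lost with limma-trend at either pseudocount (adjusted p up to 0.925). PRL and POMC had log2 changes of 0.12 (SE 0.43) and 0.082 (SE 0.53) at 12 h. At 10 h and at 14 h edgeR called 0 genes, with 41 and 21 at an unadjusted p under 0.05; DESeq2 and limma-voom each called 1 at 10 h and 0 at 14 h. In exact permutation tests CGA (adjusted p = 0.0162) and FSHB (0.0162) passed at 12 h and CGA (0.0325) at 10 h. At 10 h CGA was at 3246 CPM in 10Lv and 1190 in 10La, with the lowest library of 10Lv (2271) above the highest of 10La (2179). That result did not pass with TMM-scaled CPM (adjusted p = 0.0649). The change at 12 h was not tested against that at 10 h or 14 h. Over the 3 day lengths CGA passed in a permutation test that shuffled libraries across the day lengths and not within each (adjusted p = 0.0244). That result was lost with TMM-scaled CPM (adjusted p = 0.0925).

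FSHB had a mean log2 change of 1.79 between the arms (SE 0.48; edgeR adjusted p = 0.137), OPTN of -2.87 (SE 0.72, adjusted p = 0.103) and KIF1A, a motor of synaptic vesicle precursors, of -3.90 (SE 1.07, adjusted p = 0.144). ARHGEF11, USP54, IKZF2, MAP4K4, MAP4K3 and PICALM had adjusted p from 0.227 to 0.712. Of 6 pituitary cell markers 1 rose, and 2 with FSHB when adjusted over the list alone (camera adjusted p = 1.71e-06, and adjusted p = 0.000584 with an estimated correlation). The CGA call over the 3 day lengths was lost without a filter (adjusted p = 0.0962), and 2 genes were called without 12La replicate 6, 10La replicate 5, 10Lv replicate 1, 12Lv replicate 3 or 14Lv replicate 1 or 2.

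PTPN13, a protein tyrosine phosphatase, was higher on the rising arm in the CPM table, with 30.3 ± 17.2 CPM against 9.44 ± 9.85 (SD, n = 18 each; log2 change 2.34, SE 0.43; limma adjusted p = 0.016). That call was lost with limma-voom, with edgeR on the recovered reads, without the 6 shallowest libraries and with only the groups compared (adjusted p up to 0.566), and 2 genes were called without 16Lv replicate 2 or 4. FABP9 (adjusted p = 0.178), TSPAN2 (-0.65, SE 0.16), CCDC13, FLCN and DAAM2 on the lower side and TESMIN, FAM131A, C11orf16 and NDUFS3 on the higher did not pass (adjusted p up to 0.791). KIFC2 was higher in 10Lv than in 10La, at 31 ± 12.2 against 1.34 ± 2.82 CPM (SD, n = 6; log2 change 4.24, SE 0.68, adjusted p = 0.000876), a call lost with limma-voom (adjusted p = 0.936). Without 10La replicate 2 or 12Lv replicate 3 the 3 pairs had 2 calls. At 12 h and 14 h limma called 0 genes, with 411 and 298 at an unadjusted p under 0.05; DESeq2 called 1 and 0, limma-voom and edgeR on the recovered reads 0.

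Between the arms 5 lists of the CPM table passed in camera, none with a called member. Markers of oligodendrocytes, the cells that make myelin, were negative in 10 of 13 (median log2 change -0.11), with MBP, myelin basic protein, at -0.23 (SE 0.10) and CNP at -0.33 (SE 0.14); 1, OLIG2, passed when adjusted over the list alone (log2 change -0.56, SE 0.18; camera adjusted p = 0.0172, and adjusted p = 0.109 with an estimated correlation). The thyroid hormone pathway was positive in 6 of 8, with DIO2 at 0.92 (SE 0.37) and CRYM, a thyroid hormone binding protein, at 0.47 (SE 0.23); 1, CGA, passed when adjusted over the list alone (log2 change 0.82, SE 0.27; camera adjusted p = 0.0286, and adjusted p = 0.0895 with an estimated correlation). CGA was also the member that passed when adjusted over the pituitary cell markers alone, 4 of 4 positive (camera adjusted p = 0.0251, and adjusted p = 0.0895 with an estimated correlation). Energy balance neuropeptides were positive in 13 of 18. ADCYAP1 (PACAP; log2 change 0.40, SE 0.13) and CCK (0.41, SE 0.14) on the higher side and NPY (-0.42, SE 0.13) on the lower passed when adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.217 with an estimated correlation). Heat shock and stress genes were positive in 11 of 13, led by FKBP5, a glucocorticoid-induced chaperone (log2 change 1.28, SE 0.44), with none passing when adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.109 with an estimated correlation).

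**Figure D2:**
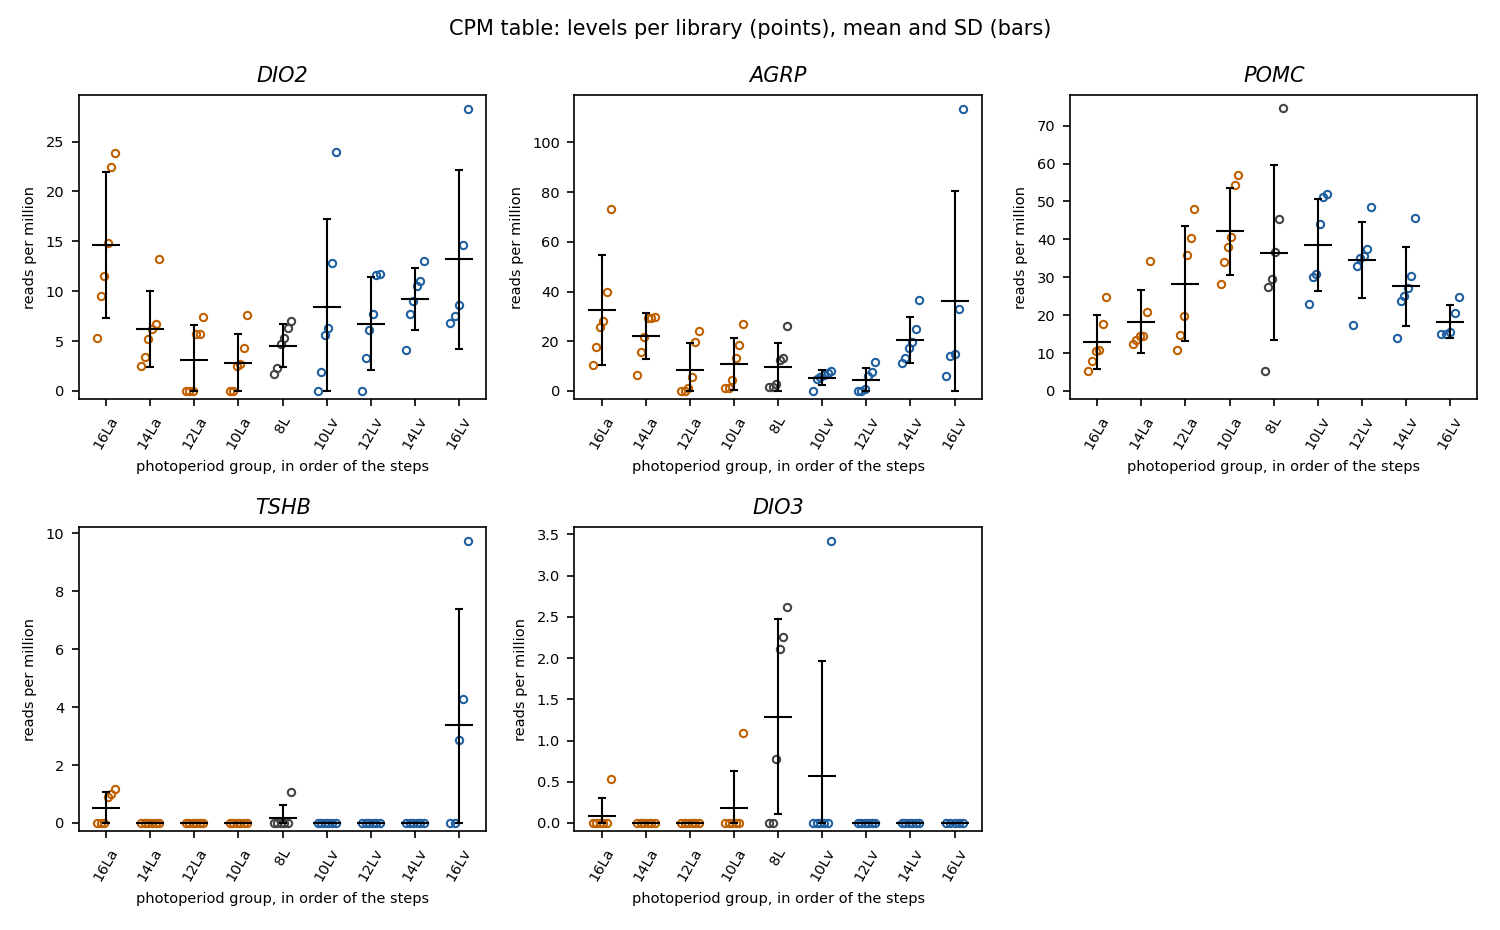
CPM of the library total (vertical axes) of DIO2, AGRP, POMC, TSHB and DIO3 in the CPM table, for the 9 photoperiod groups in the order of the steps (horizontal axes). Open points are single libraries (6 per group, 5 in 16Lv; orange for the declining arm, blue for the rising arm, grey for 8L); the long dash is the mean and the bars are 1 SD, stopped at 0. DIO2 averaged 14.6 in 16La, 2.85 in 10La (1.89 without replicate 1) and 13.2 in 16Lv, and POMC 12.9, 42.1 and 18.2 in the same groups.

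The fourth main comparison asked which transcripts followed the hours of light over the whole cycle. In the CPM table DIO2, AGRP and TSHB rose and POMC and DIO3 fell with day length in permutation tests over 53 libraries. DIO2 rose by 0.21 log2 units per hour (adjusted p = 0.00508), from 4.55 ± 2.13 CPM in 8L to 14.6 ± 7.33 in 16La (SD, n = 6 each) and 13.2 ± 8.98 in 16Lv (SD, n = 5). AGRP rose by 0.31 per hour (adjusted p = 0.00165), from 9.61 ± 9.64 CPM in 8L to 32.5 ± 22.2 in 16La and 36.3 ± 44.2 in 16Lv. The AGRP mean was 17.1 CPM in 16Lv without replicate 1 and 6.33 in 8L without replicate 2, and its slope was from 0.29 to 0.35 and passed with each library left out in turn. TSHB, with a slope of 0.096 (adjusted p = 0.00756), had reads in 3 of 6 libraries of 16La, 3 of 5 of 16Lv and 1 of 6 of 8L, and in no library of the other 6 groups, where 0 reads in a group allows up to 0.638 CPM. POMC had a slope of -0.17 (adjusted p = 0.00038), with 36.5 ± 23 CPM in 8L, and DIO3 of -0.088 (adjusted p = 0.00165), with reads in 4 of 6 libraries of 8L. The labels give no batch; within each of the 6 column positions of the table the slope had the pooled sign in 5 of 6 for DIO2, AGRP, POMC and DIO3 and in 4 of 6 for TSHB. FSHB, GNRH1, NPVF, OPN5, VIP, PRL, GH, NPY, CARTPT, TRH, EYA3, PER2, PER3 and CGA did not pass (smallest adjusted p = 0.509). In exact permutation tests between 2 groups of the CPM table, 0 of 19 priority genes passed for 8L minus 16La and for 16Lv minus 8L. The same held for each of the matched pairs and successive steps and for 16Lv minus 16La.

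Over all 8268 genes limma called 0 for the slope, with 430 at an unadjusted p under 0.05; DESeq2 called 7, limma-voom 2 and edgeR on the recovered reads 1, and limma called 1 without 14La replicate 3 or 8L replicate 3. POMC (slope -0.16, SE 0.034) and AGRP (0.32, SE 0.071) had the smallest adjusted p, 0.166 each, followed by PNPLA6 (0.40, SE 0.095, adjusted p = 0.26), PDYN (0.12, SE 0.029, adjusted p = 0.291), NMU, the precursor of the feeding peptide neuromedin U (0.22, SE 0.054, adjusted p = 0.381), and C7H2ORF66 (adjusted p = 0.457). ALG5, PAQR8 and GRIK1, a glutamate receptor subunit, had negative slopes and adjusted p up to 0.685. Energy balance neuropeptides were positive in 14 of 18 and 3 passed when adjusted over the list alone, AGRP and NMU on the higher side and POMC on the lower (camera adjusted p = 0.027, and adjusted p = 0.395 with an estimated correlation). PDYN of the reproductive neuroendocrine list also passed over its list alone (adjusted p = 0.00141). Tanycyte and ependymal markers, of the cells that line the third ventricle, were negative in 7 of 7, with CRYM at -0.070 (SE 0.037) and VIM at -0.033 (SE 0.024), none passing over the list alone (camera adjusted p = 0.038, and adjusted p = 0.395 with an estimated correlation). Nuclear genes of oxidative phosphorylation were positive in 29 of 39, led by NDUFA5 (0.038, SE 0.014), none passing over the list alone (camera adjusted p = 0.038, and adjusted p = 0.706 with an estimated correlation). Circadian clock genes were positive in 10 of 15 and did not pass (adjusted p = 0.255).

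CGA, PRL, FSHB, LOC107319226 and NELL2 rose with day length in the count table. The slope was 0.29 per hour for CGA (SE 0.033; edgeR adjusted p = 6.59e-09), 0.31 for PRL (SE 0.041, adjusted p = 1.83e-07), 0.67 for FSHB (SE 0.094, adjusted p = 1.31e-06), 0.55 for LOC107319226 (SE 0.077, adjusted p = 1.19e-06) and 0.26 for NELL2 (SE 0.063, adjusted p = 0.0226). Within the 6 column positions the slope was positive in 6 of 6 for CGA, PRL and FSHB and in 5 of 6 for NELL2. The NELL2 call was lost in 4 of 12 alternatives and without 8L replicate 5 or 16Lv replicate 4 (adjusted p up to 0.996). CTNND2 on the higher side and NAV2 (slope -0.49, SE 0.13, adjusted p = 0.0726), PTPRK, FBXO30, NAV3 and ZC3H7B on the lower did not pass. Of 6 pituitary cell markers 3 rose, also when adjusted over the list alone (camera adjusted p = 7.16e-15, and adjusted p = 1.05e-07 with an estimated correlation). In permutation tests FSHB, CGA and PRL (adjusted p = 5.00e-05 each) rose, and DIO2 (slope -0.35; adjusted p = 0.0499) fell, opposite to its direction in the CPM table. The DIO2 result was lost with a pseudocount of 0.25 and without any 1 of 33 of the 54 libraries (adjusted p up to 0.0894).

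The arms were then tested apart over 10 to 16 h of light, with 8L left out so that they shared no library. On the declining arm CGA (slope 0.50, SE 0.059; edgeR adjusted p = 2.32e-08), LOC107319226 (0.81, SE 0.14), PRL (0.37, SE 0.070) and FSHB (0.72, SE 0.14) were higher on longer days in the count table, and NAV2, a neuron navigator protein, was lower (-1.25, SE 0.29, adjusted p = 0.0147). The NAV2 call was lost with limma-trend at either pseudocount and with only the groups compared (adjusted p up to 0.338). From 10Lv to 16Lv on the rising arm edgeR called 0 genes, with 58 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With 8L in both arms edgeR called 4 genes on the rising arm, FSHB (slope 0.69, SE 0.12, adjusted p = 0.000343), CGA (0.23, SE 0.040, adjusted p = 0.000343), PRL (0.26, SE 0.049, adjusted p = 0.000648) and LOC107319226 (0.46, SE 0.094, adjusted p = 0.00275), and 8 on the declining arm. Over 10 to 16 h the slopes differed between the arms for CGA (rising minus declining -0.43, SE 0.079, adjusted p = 0.00142). That call was lost with 8L in both arms (-0.14, SE 0.043, adjusted p = 0.276), where edgeR called 0 genes, with 43 at an unadjusted p under 0.05. It was also lost without the 9 libraries with few transcripts, without those under 1/3 of the median total and without a filter, and 2 genes were called without 10La replicate 1. KIFC2 of the CPM table was higher on longer days of the declining arm (slope 0.57, SE 0.11; limma adjusted p = 0.024), a call lost in 5 of 14 alternatives, with 8L in the arm among them (slope 0.28, SE 0.076, adjusted p = 1), and without any 1 of 16La replicates 2, 4 and 5 and 10La replicates 1, 3, 4 and 6 (0 calls each). Leaving out 16La replicate 3, 14La replicate 3, 12La replicate 2 or 8L replicate 2 or 3 gave 2 calls. For the rising arm and for the difference limma called 0, with 485 and 373 at an unadjusted p under 0.05; DESeq2 called 0 and 1, and limma-voom and edgeR on the recovered reads 0. Without 16Lv replicate 4 limma called 1 in each. With 8L in both arms limma called FABP9 for the difference (-0.34, SE 0.049, adjusted p = 7.62e-05).

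Between successive steps of the count table edgeR called genes from 14La to 12La, from 8L to 10Lv and from 10Lv to 12Lv. From 14La to 12La, CGA fell from 7890 ± 3088 to 1033 ± 338 CPM (SD, n = 6; log2 change -2.89, SE 0.37; edgeR adjusted p = 3.67e-07), FSHB from 420 ± 256 to 30.1 ± 36.8 (log2 change -3.62, SE 0.84, adjusted p = 0.0257) and LOC107319226 by a log2 change of -4.27 (SE 0.84, adjusted p = 0.00255). From 8L to 10Lv, FSHB rose to 114 ± 139 CPM, on 14 counts in 4 of 6 libraries (edgeR adjusted p = 0.0231). FSHB did not pass the exact permutation test at that step. From 10Lv to 12Lv LOC107319226 rose (log2 change 4.72, SE 0.90, edgeR adjusted p = 0.00289). In exact permutation tests CGA and FSHB also rose from 10Lv to 12Lv (adjusted p = 0.0162 each), CGA from 8L to 10Lv (0.0325), and FSHB fell from 12Lv to 14Lv, to 148 ± 79 CPM (0.0325), and POMC from 16La to 14La (0.0325). With TMM-scaled CPM the tests of CGA from 8L to 10Lv (adjusted p = 0.0974) and of POMC from 16La to 14La (adjusted p = 0.13) did not pass, while PRL passed from 14La to 12La (adjusted p = 0.0433, against 0.0541) and from 10Lv to 12Lv (adjusted p = 0.0325, against 0.303). Without 12La replicate 3 the FSHB mean in 12La was 18.2 CPM. The LOC107319226 calls were lost with limma-trend at either pseudocount, and that from 10Lv to 12Lv also with no filter (adjusted p up to 1 and 0.719). The FSHB calls at both steps were lost in 5 of 12 alternatives each and without any 1 of 7 libraries of the groups compared, with adjusted p up to 0.405.

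Of the 8 steps, 3 had a call in the CPM table. C7H2ORF66 fell from 21.3 ± 11.2 CPM in 14La to 1.44 ± 1.27 in 12La (SD, n = 6, log2 change -3.25, SE 0.53, limma adjusted p = 0.0016). This call held in each of the 12 alternatives that gave the gene an adjusted p, which was not every alternative run. KIFC2 fell from 20.5 ± 11.9 CPM in 12La to 1.34 ± 2.82 in 10La (log2 change -3.55, SE 0.68, adjusted p = 0.0302), a call lost in 3 of 12 alternatives and without any 1 of 9 libraries of those groups. Without 12La replicate 1, 4 or 5 or 10La replicate 1, 2, 3, 4 or 6 the steps had 1 call in all. MAPK8IP1 fell from 45.4 ± 13.7 in 14Lv to 13.3 ± 12.5 in 16Lv (log2 change -2.76, SE 0.54, adjusted p = 0.043), a call kept in 4 of 13 alternatives and in 15 of 53 fits that left out 1 library.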

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

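Chosen only after the result was seen were the test of pituitary markers between the tables and the test of FABP9 against the step number, each also without the genes or groups that prompted it, and leaving out the 9 libraries, blocking on column position and putting 8L in both arms were added after the data had been seen.

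The 2 tables describe the same birds but not the same profile, with 36000 counts of PRL in the count table and 39 reads of it in the CPM table. If both tables counted the same libraries in different ways, a bird's deviation from its group would be shared, yet the median correlation over 672 genes and 52 birds was 0.011 (permutation p = 0.279), a value that swapped bird names would also give. Names or counting that hid all pituitary genes to the same degree would leave the POMC to CGA ratio alike. Yet it differed between the tables by 4.39 log2 units (SE 0.282) whichever bird a column belongs to. Names or counting that hid single genes could change the ratio, so the ratio cannot decide on that. Reads of pituitary tissue in the count table are a candidate explanation. Each gene's log2 difference between the tables (count table minus CPM table) was taken relative to the median gene measured in both. It was positive for 11 of 12 fixed pituitary markers, with a median of 6.36 (permutation p = 0.0001 against 10000 random lists, the smallest they can give). Without PRL, FSHB, POMC and CGA, the genes that prompted the test, it was positive for 7 of 8 (median 5.46, permutation p = 0.0001). The median of 12 hypothalamic region markers was -2.06. POMC, CGA and CHGA also passed the filter of the CPM table, and how the tissue was divided between the tables was not analysed here.

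CGA and FSHB stood lower at 12 h on the declining arm than on the rising arm in the count table. A different share of pituitary tissue would move the other pituitary markers by about as much, yet the mean of log2 CPM over POMC, CHGA and PRL differed by 0.165 between the libraries of the groups (SE 0.553), and the edgeR fits gave 0.0821, -0.0203 and 0.124. Without the 9 libraries with few transcripts the CGA change was 3.08 (SE 0.417; edgeR adjusted p = 4.92e-06), and with the column position as a block 2.76 (SE 0.303; adjusted p = 9.17e-09), so neither removed it. The direction of the change in day length is 1 biological hypothesis, which may be followed up with CGA and FSHB, found and tested on the same data. Birds of the rising arm were sampled at later steps, after the shortest days. Direction therefore runs together with age, time in the study and earlier short days, and these cannot be told apart in this design. A change in the share of gonadotroph and thyrotroph cells, the pituitary cells that make CGA, was not tested.

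FABP9 stood lower at 16 h of light after the cycle than before it in the CPM table. Reads shared with other FABP genes would raise another of them, yet the highest change among FABP3, FABP5, FABP6 and FABP7 was -0.0984 (FABP5), and FABP3 was lower too (log2 change -0.57, SE 0.19). Depth does not account for it, since without the libraries under 1/3 of the median depth the change was -2.82 (SE 0.466; limma adjusted p = 0.00276). At fixed hours of light FABP9 had a slope of -0.303 log2 units per step (permutation p = 1e-05, the smallest possible), and of -0.249 (SE 0.038; permutation p = 1e-05) without 16La and 16Lv, which prompted the test, a pattern consistent with a steady change over time. Age and the order of the steps run together in this design, and their effects were not tested apart.

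The slope of CGA on hours of light differed between the arms over 10 to 16 h (rising minus declining -0.428, SE 0.079; edgeR adjusted p = 0.00142), and no longer passed with 8L in both arms (-0.135, SE 0.043; adjusted p = 0.276). Single libraries far from the other 5 of their group were found in 18 of 178 tests of a gene in a group, where chance at 1 in 20 gives 8.9. That expectation holds for normally distributed values, which low counts are not. Depth limits several of the zeros: 1 read was 3.42 CPM in 10Lv replicate 3 of the CPM table. Replicate 5 of 14Lv in the count table had 9101 counts in all. In a group with 5 zeros any positive value is flagged, as for EYA3 in 10Lv replicate 1. Those of the CPM table were AGRP at 0 CPM (others from 4.72 to 7.99) and EYA3 at 0 (from 43.1 to 210) in 10Lv replicate 3, CARTPT at 35.8 in 14Lv replicate 3 (from 12.2 to 18.3) and PER2 at 2.66 in 8L replicate 3 (from 39.3 to 152). Of the count table, replicate 5 of 14Lv had FSHB at 0 (others from 152 to 238), TSHB at 0 (from 25.7 to 95.7) and PRL at 4505 (from 17525 to 24361). In 10La replicate 2 TSHB was at 0 (others from 38.7 to 108), PER3 at 0 (from 35.9 to 224) and POMC at 2196 (from 19266 to 31341). In 8L replicate 5 TSHB was at 0 (from 61.8 to 148), PER3 at 0 (from 82.6 to 558) and POMC at 3000 (from 16999 to 39961), and in 12Lv replicate 5 POMC was at 2477 (from 15179 to 25735) and PRL at 1541 (from 11710 to 15845). These 4 libraries are among the 9 with few detected transcripts. The others were POMC at 5023 in 14La replicate 3 (from 9098 to 12646), EYA3 at 35.3 in 10Lv replicate 1 (0 in the other 5) and PER2 at 0 in 14La replicate 6 (from 219 to 496).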

How the results depend on the processing

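The alternatives chosen after the data were seen were edgeR, DESeq2 and limma-voom on the recovered reads of the CPM table, the column position as a block, transcripts in place of genes, leaving out the 9 libraries with few transcripts, 8L in both arms and keeping the near-identical 16Lv columns apart. Over 66 counts of calls and alternatives other than leaving out 1 library, 435 values were made, of which 325 stayed within 1.5 times the reported count and 110 moved. The 325 include counts of 0 that stayed at 0, so their share does not measure how well calls held. Of 109 results for named genes 0 reversed in direction, and 40 had passed. These genes were named by small p in the same libraries, and the difference among groups has no direction. The 0 therefore does not measure how well their directions held. In the count table CGA and PRL passed for 8L minus 16La in 14 of 14 alternatives, with log2 changes from -2.45 to -2.09 and from -2.82 to -2.35, and CGA at 12 h in 13 of 13. Depth set what a count of 0 allows, up to 12.1 CPM for FSHB in 8L of the count table. In data simulated at the observed depth, spread and number of libraries the count table's test recovered 26.9% of 4-fold changes for 8L minus 16La and the CPM table's 49.3%, and the part of depth in this was not tested. With no filter the genes tested went to 16442 in the count table and 19902 in the CPM table, and with a mean of at least 20 to 169 and 4138, so that fewer genes could be called in the latter. For the other changes the cause was not tested.

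Values are counts of called genes, as reported and under the alternative. With DESeq2 size factors the CPM table went from 0 to 1 for 16Lv minus 8L. With no filter the CPM table went from 3 to 5 for the difference among groups, 0 to 1 for 8L minus 16La, 0 to 3 for 16Lv minus 8L, 2 to 22 for 16Lv minus 16La, 1 to 0 for the declining slope and 3 to 28 for the successive steps. The count table went from 4 to 1449 for the difference among groups, 4 to 24 for 8L minus 16La, 2 to 23 for 16Lv minus 8L, 0 to 32 for 16Lv minus 16La, 1 to 167 for rising minus declining, 3 to 56 for the matched pairs, 5 to 57 for the slope, 5 to 74 for the declining slope, 0 to 28 for the rising slope, 1 to 74 for the slope difference and 5 to 142 for the successive steps. With a mean of at least 20 the CPM table went from 3 to 1 for the difference among groups, 0 to 1 for 16Lv minus 8L, 1 to 0 for the matched pairs, 1 to 0 for the declining slope and 3 to 1 for the successive steps. For the count table values went from 4 to 2 for the difference among groups, 4 to 2 for 8L minus 16La, 5 to 2 for the slope, 5 to 2 for the declining slope and 5 to 1 for the successive steps. With DESeq2 the CPM table went from 3 to 16 for the difference among groups, 0 to 1 for 16Lv minus 8L, 1 to 2 for rising minus declining, 1 to 2 for the matched pairs, 0 to 7 for the slope, 1 to 3 for the declining slope, 0 to 1 for the slope difference and 3 to 10 for the successive steps. Counts of the count table went from 4 to 7 for 8L minus 16La, 2 to 6 for 16Lv minus 8L, 1 to 2 for rising minus declining and 5 to 11 for the successive steps. With limma-voom the CPM table went from 2 to 0 for 16Lv minus 16La, 1 to 0 for rising minus declining, 1 to 0 for the matched pairs, 0 to 2 for the slope, 1 to 0 for the declining slope and 3 to 1 for the successive steps. The count table went from 4 to 8 for the difference among groups, 2 to 1 for 16Lv minus 8L and 3 to 10 for the matched pairs. With 2 surrogate variables the CPM table went from 2 to 1 for 16Lv minus 16La and 1 to 3 for the matched pairs, and the count table from 4 to 10 for the difference among groups. Without libraries under 1/3 of the median total the CPM table went from 2 to 1 for 16Lv minus 16La, 1 to 0 for rising minus declining, 1 to 0 for the declining slope and 3 to 1 for the successive steps, and the count table from 1 to 0 for the slope difference. With edgeR on the recovered reads the CPM table went from 3 to 5 for the difference among groups, 2 to 1 for 16Lv minus 16La, 1 to 0 for rising minus declining, 1 to 2 for the matched pairs, 0 to 1 for the slope and 1 to 0 for the declining slope. With the near-identical 16Lv columns kept apart the CPM table went from 0 to 1 for 16Lv minus 8L. With the column position as a block the CPM table went from 0 to 1 for 16Lv minus 8L, and the count table from 1 to 2 for rising minus declining, 3 to 5 for the matched pairs and 5 to 9 for the successive steps. With only the groups compared in the fit the CPM table went from 2 to 1 for 16Lv minus 16La, and the count table from 2 to 0 for 16Lv minus 8L. With 8L in both arms the CPM table went from 1 to 0 for the declining slope and 0 to 1 for the slope difference, and the count table from 5 to 8 for the declining slope, 0 to 4 for the rising slope and 1 to 0 for the slope difference. With limma-trend and a pseudocount of 1 the count table went from 5 to 1 for the successive steps. With limma-trend and a pseudocount of 0.25 the count table went from 5 to 1 for the successive steps. With transcripts in place of genes the count table went from 4 to 7 for the difference among groups, 2 to 5 for 16Lv minus 8L, 1 to 2 for rising minus declining, 3 to 5 for the matched pairs and 5 to 8 for the successive steps. Without the 9 libraries with few transcripts the count table went from 2 to 4 for 16Lv minus 8L, 1 to 0 for the slope difference and 5 to 3 for the successive steps.

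For the counts of lists called by camera, the values were as follows. With an estimated correlation the CPM table went from 1 to 0 for 8L minus 16La, 5 to 0 for rising minus declining and 3 to 0 for the slope, and the count table from 2 to 1 for 8L minus 16La, 2 to 1 for 16Lv minus 8L and 1 to 0 for 16Lv minus 16La. With fry the CPM table went from 1 to 0 for 8L minus 16La, 5 to 0 for rising minus declining and 3 to 0 for the slope, and the count table from 2 to 1 for 8L minus 16La, 2 to 1 for 16Lv minus 8L and 1 to 0 for 16Lv minus 16La. With library totals the CPM table went from 1 to 2 for 8L minus 16La and 3 to 1 for the slope, and the count table from 1 to 2 for rising minus declining. Without members shared with another list the CPM table went from 5 to 2 for rising minus declining and 3 to 1 for the slope. With DESeq2 size factors the CPM table went from 3 to 1 for the slope, and the count table from 1 to 2 for 16Lv minus 16La and 1 to 2 for rising minus declining. For priority genes passing in permutation tests, with TMM-scaled CPM the CPM table went from 0 to 1 for 14Lv minus 12Lv, and the count table from 1 to 0 for rising minus declining, 1 to 0 for 10Lv minus 10La, 1 to 0 for 14La minus 16La and 1 to 0 for 10Lv minus 8L.

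Leaving out each library in turn gave these ranges of called genes. In the CPM table the range was 2 to 5 for the difference among groups, 0 to 1 for 8L minus 16La, 0 to 2 for 16Lv minus 8L, 1 to 3 for 16Lv minus 16La, 1 to 2 for rising minus declining, 1 to 2 for the matched pairs, 0 to 1 for the slope, 0 to 2 for the declining slope, 0 to 1 for the rising slope, 0 to 1 for the slope difference and 1 to 4 for the successive steps. In the count table the range was 4 to 5 for the difference among groups, 4 to 6 for 8L minus 16La, 1 to 3 for 16Lv minus 8L, 0 to 0 for 16Lv minus 16La, 1 to 2 for rising minus declining, 3 to 4 for the matched pairs, 4 to 6 for the slope, 5 to 6 for the declining slope, 0 to 0 for the rising slope, 1 to 2 for the slope difference and 4 to 6 for the successive steps.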

Other observations

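The tests of single members over their list alone were planned, and the comparison of column positions was chosen only after the data had been seen.

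Other gene groups of the CPM table had single members that passed when adjusted over their list alone, and limma called none of those named here over all genes. Among glial and fibroblast markers SLC1A2, a glutamate transporter of astrocytes, rose with day length (slope 0.064 per hour, SE 0.020; limma list adjusted p = 0.023), as did PTGDS, a prostaglandin synthase (0.067, SE 0.022; list adjusted p = 0.0312). PTGDS was also higher at 16Lv than at 8L (log2 change 0.92, SE 0.26; list adjusted p = 0.00556), and the heat shock protein HSPH1 was lower (-0.74, SE 0.22; list adjusted p = 0.021). CYP19A1, which makes estrogens, was higher on the rising arm at matched day length (1.28, SE 0.39; list adjusted p = 0.0208). The collagens moved apart there, COL1A2 up (0.90, SE 0.34; list adjusted p = 0.0391) and COL3A1 down (-1.84, SE 0.63; list adjusted p = 0.0359).

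Each count of called genes was set against 100 splits of the same libraries into groups of the same sizes, the real one included. For each, the number of splits as large is given first, then the real count against the highest other.

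For the count table fewer than 5 of the 100 splits were as large for the difference among groups (1 split, 4 against 2) and 8L minus 16La (1 split, 4 against 2). The same held for 16Lv minus 8L (3 splits, 2 against 5) and the matched pairs (2 splits, 3 against 3). It also held for the slope (1 split, 5 against 3), the declining slope (1 split, 5 against 1) and the successive steps (2 splits, 5 against 15). Where 1 split is given, it is the real one. For 16Lv minus 8L, the matched pairs and the successive steps another split equalled or exceeded the real count, so chance was not excluded. The bound of 5 was not adjusted over the comparisons. More than 5 splits were as large for rising minus declining (10 splits, 1 against 9) and the slope difference (9 splits, 1 against 2). For 16Lv minus 16La and the rising slope edgeR called 0 genes (48 and 58 at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom), so 100 splits were as large, with 0 and 2 as the highest other.

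For the CPM table fewer than 5 of the 100 splits were as large for 16Lv minus 16La (4 splits, 2 against 23) and rising minus declining (3 splits, 1 against 1). The same held for the declining slope (2 splits, 1 against 1). In each of these another split equalled or exceeded the real count, so chance was not excluded. At least 5 splits were as large for the difference among groups (5 splits, 3 against 4), the matched pairs (15 splits, 1 against 1) and the successive steps (18 splits, 3 against 44). Where limma called 0 genes 100 splits were as large. The highest other was 1 for 8L minus 16La (350 at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom) and 19 for 16Lv minus 8L (447, DESeq2 1, limma-voom 0). It was 1 for the slope (430, DESeq2 7, limma-voom 2), 3 for the rising slope (485, DESeq2 0, limma-voom 0) and 2 for the slope difference (373, DESeq2 1, limma-voom 0). Among the other splits of the CPM table, those with any call ranged from 1 for the declining slope to 50 for the successive steps. They numbered 14 each for 16Lv minus 8L and 16Lv minus 16La. The 0 calls in simulated data with no change therefore do not carry over to these libraries. Single splits had 9 and 15 genes in the count table and 19, 23 and 44 in the CPM table, more than the real counts. Whether a structure of the samples lies behind these was not tested.

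Libraries at the same column position within their groups had residuals with a mean correlation of 0.0839 in the count table, against -0.0167 at other positions, and 0.26 at position 6. The values in the CPM table were 0.026 and -0.00411. Of the 9 count table libraries with few transcripts 7 stood at position 6, and of the 6 CPM table libraries under 1/3 of the median total 5 stood at position 4. Every group of the CPM table had a shallow library, from 251382 reads (16La replicate 2) to 379261 (14La replicate 3). The lowest of the remaining libraries had 626002 (10Lv replicate 4). The shallow library stood at position 3 in 10La and at position 4 elsewhere. Those of 14La, 8L and 12Lv lay above the bound of 1/3 and were not left out. Whether these libraries form a batch was not tested.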
